A study of Mus musculus with 18 samples.

How the data were processed

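Gene expression was measured by RNA sequencing in 18 libraries of mouse CD8 T cells, sorted per the labels into naive cells with low surface CD44 and memory-phenotype cells with high surface CD44. Wild-type mice gave 4 naive and 4 memory libraries, and mice homozygous for the Hsd allele of Dock2, called Dock2-deficient in the labels, gave 5 naive and 5 memory libraries. Groups and replicate numbers were taken from the sample titles. The labels did not say that replicates were separate animals, so p-values measure only the spread between these libraries, part of which may be technical. The strain field named C57BL/6J for all 18 libraries, while the descriptions of the Dock2-deficient libraries carried the name C57L6NHsd, so a difference in substrain could not be separated from genotype.

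RNA was extracted with a Qiagen RNAeasy kit and libraries were made with Smartseq2, a full-length cDNA method that does not mark strand, per the labels' protocols. The genome build was mm10, and bcl2fastq, FastQC and RSEM were used, per the submitters' processing notes. Tool versions, the aligner settings and the gene annotation were not given in the sources used here. The deposited table held 46983 genes as a normalized signal, that is, RSEM expected counts which the authors had scaled between libraries. All values in every library (100%) lay on a grid of steps of 0.01 reads divided by a factor of the library, and the factor read from the grid equalled the library's median ratio over 8606 genes above 0 in all 18 libraries, with a largest relative difference of 3.55e-15. Between 59.5% and 69.3% of the values above 0 came out as whole reads within 0.005, the others being fractional expected counts. Count models, which could have used rounded expected counts, were not run. Every column of the table belonged to a library of the series.

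Depth was read back as the expected reads per library, the values multiplied by the recovered factor. It ranged from 2215987 to 8257768 reads. Rn18s-rs5, a ribosomal RNA gene, took on average 58.5% of a library (37.0% to 69.4%). Between 12363 and 14548 genes were above 0 in a library. Gene positions came from GENCODE M21 on mm10, in which 46488 of the identifiers (98.9%) were found. Reads of near-identical gene copies are shared out by RSEM as estimates, so values of the Klra, Ly6c, Gbp, Ctla2, Serpinb6 and Pydc families are uncertain. No 2 libraries of a group were alike within sampling noise: the chi-square per degree of freedom between them was 4.94 to 79.9, and the Pearson correlation of log2 values was 0.926 to 0.969.

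Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3. Fold changes are on this scale, which understates the change of low genes. Genes with a value of at least 10 in at least 4 libraries were kept, which left 9437. A single linear model with 1 mean per group was fitted to all 18 libraries, with 14 residual degrees of freedom and variances moderated along a trend with mean expression (6.43 prior degrees of freedom). Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values from limma with a threshold of 0.05. The 5 comparisons were memory against naive in wild type, memory against naive in Dock2-deficient mice, Dock2-deficient against wild type in naive cells, the same in memory cells, and the difference between these differences (the interaction). The 2 memory comparisons shared no libraries, nor did the 2 genotype comparisons. Groups were said not to overlap where every library of a group lay above every library of the other. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation and plots.

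The fit was checked on simulated values with 50 genes changed by each size, drawn from those with a mean of at least 50 over the 18 libraries. Genes were simulated independently, with no shared shift of a library other than its depth. For memory against naive, 24% of the genes changed 2-fold were called in wild type (9228 genes) and 42% in Dock2-deficient mice (9202 genes), and 92% and 90% of those changed 4-fold. For the genotype comparisons, 48% of the genes changed 2-fold were called in naive cells (9205 genes) and 50% in memory cells (9216 genes), and 92% and 94% of those changed 4-fold. Between 5 and 9 unchanged genes were called in each simulation. The detection rates do not cover changed genes with a mean under 50, and the false calls leave out structure between real libraries.

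The following choices were made before the data were examined: the test, the filter, the genes to be named, 27 gene lists and most of the alternatives. Named were, in each comparison of a pair of groups, the 10 genes with the largest log2 fold change in each direction among those past the threshold with a mean of at least 50 over the 18 libraries and groups that did not overlap, without unnamed gene models, pseudogenes and receptor segments. For the interaction, up to 5 genes in each direction were taken without the condition on overlap. Up to 4 members of each list with the smallest p, a fixed set of marker genes and Dock2 were added. The lists covered naive and quiescence genes, memory and effector-memory genes, natural killer receptors, cytotoxic and effector molecules, T cell receptor (TCR) signal strength reporters, inhibitory receptors and exhaustion-associated genes, TCR proximal signalling components, DOCK and Rac pathway and actin regulators, chemokine receptors and homing molecules, cytokine receptors and STAT signalling, interferon-stimulated genes, cell cycle genes, glycolysis genes, oxidative phosphorylation and fatty acid oxidation genes, survival and apoptosis genes, ribosomal protein genes, mitochondrially encoded genes, and immediate early and cell handling stress genes. Markers of B cells, myeloid and dendritic cells, natural killer (NK) and innate lymphocytes, CD4 and regulatory T cells, gamma delta and natural killer T cells, and red cells and platelets stood for cells other than CD8 T cells. Sex-linked genes, genes that differ between C57BL/6J and C57BL/6N, and chromosome 11 neighbours of Dock2 were technical checks.

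Each list was tested against the other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone. Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, quantile normalization, upper quartile scaling, only the libraries compared, robust moderation, weights per library, the replicate number as a block, and leaving out each library in turn. Added after the data had been seen were limma's voom weights on the recovered expected counts, sex as a covariate, removal of a trend with transcript length, the share of Rn18s-rs5 as a covariate, and the fits without wild-type memory library 4 and Dock2-deficient memory library 5. Some named genes are not reported here. Genes under the filter were left out of the tests, and no library was left out of the main results.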

Results

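The series asked how the transcriptomes of naive and memory-phenotype CD8 T cells differ between wild-type mice and mice deficient in Dock2, a guanine nucleotide exchange factor that activates Rac in blood cells and couples receptors to the actin cytoskeleton. There were 4 wild-type naive, 4 wild-type memory, 5 Dock2-deficient naive and 5 Dock2-deficient memory libraries. Mitochondrial transcripts took on average 5.42%, 5.65%, 4.23% and 5.05% of the expected reads in these groups, and the ribosomal RNA gene Rn18s-rs5 58.6%, 60.2%, 61.4% and 54.2%. The first 3 principal components held 19.9%, 17.5% and 10.8% of the variance. Wild-type memory library 4 lay apart on the second (113.9, other libraries at most 22.5) and Dock2-deficient memory library 5 lay farthest out on the first (82.8).

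Dock2 (ENSMUSG00000020143, chromosome 11, 34226815 to 34783892, minus strand, mm10) was read first as a check of the labels. Its normalized expected count was 514, 422, 329.7 and 288 in the wild-type naive libraries and 444, 459, 399.7 and 844 in the wild-type memory libraries. It was 295.9, 202, 373, 174 and 171 in the Dock2-deficient naive libraries and 225, 207, 148, 279.6 and 61.0 in the Dock2-deficient memory libraries. The means were 388 ± 101 (SD, n = 4) and 243 ± 88.5 (SD, n = 5) in naive cells. The log2 fold change of -0.71 ± 0.36 (SE) did not pass the test (adjusted p = 0.841), and the groups overlapped. In memory cells they were 537 ± 206 (SD, n = 4) and 184 ± 83.4 (SD, n = 5). Although the groups did not overlap, the log2 fold change of -1.64 ± 0.36 did not pass either (adjusted p = 0.121). Dock2 RNA was thus present in every library, and the amount of protein was not measured. The 10 tested chromosome 11 neighbours of Dock2 had median log2 fold changes of -0.06 in naive cells (adjusted p = 0.92) and -0.19 in memory cells (adjusted p = 0.66).

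**Figure D1:**
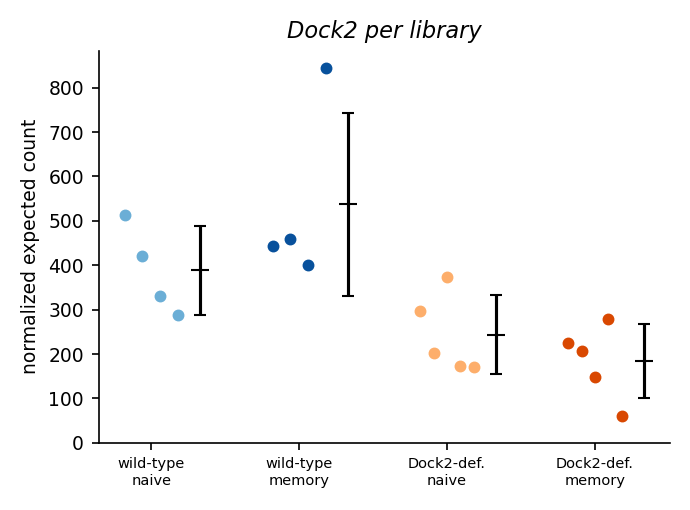
Dock2 per library as normalized expected counts, with each point a library and the bars giving mean ± SD per group (n = 4 or 5). The 5 Dock2-deficient memory libraries (61.0 to 279.6) lie below the 4 wild-type memory libraries (399.7 to 844), while the naive groups overlap.

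The sexes of the mice were not evenly spread. Xist, transcribed from the inactive X chromosome, was 1820.4 to 3409.6 in the wild-type naive and 2760.2 to 3887 in the wild-type memory libraries. It was 2217 and 2593 in Dock2-deficient naive and memory library 1, and 0 to 5.44 in the other 4 libraries of each Dock2-deficient group, which held the Y-linked genes instead (summed value 184 to 273 in naive and 167 to 262 in memory libraries). All 8 wild-type libraries thus read as female, and 4 of the 5 libraries in each Dock2-deficient group read as male. The sex-linked genes had median log2 fold changes of 2.92 in naive cells (mean 0.60, adjusted p = 0.066; adjusted over the list alone, 4 higher and 2 lower) and 2.73 in memory cells (adjusted p = 0.27).

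Memory-phenotype cells of wild-type mice differed from naive cells by higher expression of memory, cytotoxic and natural killer receptor genes and lower expression of naive and quiescence genes. Ccl5, a chemokine stored by memory CD8 T cells, rose from 3.29 ± 2.48 to 1733 ± 413 (SD, n = 4 each; log2 fold change 8.94 ± 0.55, adjusted p = 1.7e-09). Tbx21, which encodes the effector transcription factor T-bet, rose from 7.44 ± 7.24 to 509 ± 122 (6.21 ± 0.40, adjusted p = 2.0e-09). Cxcr3, a chemokine receptor that guides T cells to inflamed tissue, rose from 4.11 ± 3.06 to 284 ± 23.5 (5.99 ± 0.47, adjusted p = 2.8e-08). The gut-homing receptor gene Ccr9 fell from 368 ± 94.1 to 2.35 ± 2.17 (-7.04 ± 0.46, adjusted p = 2.7e-09). Itgae, which encodes the integrin chain CD103, fell from 268 ± 56.0 to 14.0 ± 13.2 (-4.52 ± 0.56, adjusted p = 2.1e-05). Cd44, the gene of the sorting marker, rose as the gate requires (4.71 ± 0.58). In all, 238 of the 9437 genes passed limma's test, 177 higher and 61 lower in memory cells. Of these, 220 changed at least 2-fold. The groups did not overlap for 780 genes (8.27%, against 2.86% by chance).

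The memory and effector-memory list rose as a group, with a median log2 fold change of 2.90 (adjusted p = 1.2e-40). Of 28 tested members, 19 were higher and none lower over all genes, and 24 were higher adjusted over the list alone. Il2rb, the receptor chain for IL-2 and IL-15, rose from 309.9 ± 71.7 to 3804 ± 512 (SD, n = 4 each). Il18rap, a subunit of the IL-18 receptor, rose by 6.10, and Eomes, a transcription factor related to T-bet, by 2.89 on the log2 scale. Natural killer receptors rose, 12 of 15 (12 adjusted over the list alone; median 4.78, adjusted p = 1.5e-29), a median that rests in part on genes listed at 0 in naive cells. Klrc1, which encodes the inhibitory receptor NKG2A, was listed at 0 in all 4 naive libraries and at 93.2 ± 11.9 (SD, n = 4) in memory cells. Klrk1, which encodes the activating receptor NKG2D, rose by 3.17. Cytotoxic and effector molecules rose in 7 of 17 (14 adjusted over the list alone; median 1.35, adjusted p = 1.2e-17). Among them Gzmm, a granzyme, rose by 6.27 and the chemokine genes Xcl1 and Ccl4 by 3.22 and 3.47. The markers of NK and innate lymphocytes rose alongside (3 of 7, adjusted over the list alone 6; median 2.32, adjusted p = 9.9e-09). Its members Ncr1, Tyrobp and Klrb1f were under the filter and averaged 0 in naive and 2.725, 4.795 and 1.589 in memory cells. This list test thus does not show NK cells in the memory sort. The markers of gamma delta and natural killer T cells rose as well (5 of 6, adjusted over the list alone 5 higher and 1 lower; median 3.004, adjusted p = 9.9e-09). Among the latter, Cd163l1, a scavenger receptor gene, was listed at 0 in all naive libraries and at 61.9 ± 26.4 in memory cells, and Tcrg-C2 rose by 3.15. The CD4 and regulatory T cell markers also rose (median 1.27, adjusted p = 6.2e-06). The member called over all genes was Cxcr5 (4.66), a follicle-homing receptor, and 3 of 4 were called adjusted over the list alone. The other members tested were Ikzf2, Icos and Gata3. Cd4, Zbtb7b, Foxp3 and Cd40lg were under the filter. They averaged 0, 0, 3.81 and 1.13 in naive and 2.22, 1.72, 2.21 and 0.365 in memory cells. The list test thus does not show CD4 T cells in the memory sort.

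Naive and quiescence genes fell as a group (median -0.21, mean -0.94, adjusted p = 6.2e-06). Of 21 members 7 were lower and 1 higher, and 8 were lower and 2 higher adjusted over the list alone. Besides Ccr9 and Itgae, the members that fell included Igfbp4 (-3.84), Dapl1 (-1.73) and the lymph node homing receptor gene Ccr7 (adjusted p = 0.0092). Id3, chosen after its value was seen, rose by 1.13, a call kept in 2 of 8 fits that left out a library (adjusted p up to 0.118, without naive library 3). Lef1 fell by 0.92 (adjusted p = 0.0281), a call lost without naive library 1, 3 or 4 or memory library 1, 2 or 3 (adjusted p up to 0.106). Tcf7, which encodes the transcription factor TCF-1, did not pass (-0.21, adjusted p = 0.764). The TCR signal strength reporters rose (3 of 20, adjusted over the list alone 6; median 0.55, adjusted p = 9.3e-06), the called members being Ccl4, Xcl1 and Ly6c1 rather than Nr4a1 (0.21, adjusted p = 0.922). Ccl4 and Xcl1 also belong to the list of cytotoxic and effector molecules, so the list test does not show stronger TCR signalling. Inhibitory receptors rose in 2 of 8 (4 adjusted over the list alone; median 1.10, adjusted p = 8.3e-05), namely Cd160 (2.18) and Cd101 (2.46). Chemokine receptors and homing molecules went both ways, 7 higher and 3 lower of 23 (10 and 4 adjusted over the list alone; median 0.62, adjusted p = 0.0018). Cell cycle genes rose in 2 of 15 (3 adjusted over the list alone; median 0.20, adjusted p = 0.027), a call lost without wild-type memory library 4 and Dock2-deficient memory library 5 (adjusted p = 0.131). The proliferation marker Mki67 was 1.73 ± 2.60 in naive and 23.9 ± 12.3 in memory cells (adjusted p = 0.012; up to 0.057 without naive library 2 or 4 or memory library 4). Cytokine receptors and STAT genes had 8 higher and 2 lower of 36 (10 and 4 adjusted over the list alone; median 0.31, adjusted p = 4.1e-04), a call lost at adjusted p = 0.058 with an estimated correlation. Of the interferon gamma receptor chains, Ifngr1 rose by 1.54 and Ifngr2 fell by 3.83. The other 11 lists called here hold with an estimated correlation.

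The same comparison in Dock2-deficient mice gave 266 genes, 167 higher and 99 lower in memory cells, of which 230 changed at least 2-fold. Gzmm rose from 1.76 ± 2.67 to 303.5 ± 69.8 (SD, n = 5 each; 7.19 ± 0.48, adjusted p = 6.2e-09) and Ccl5 from 46.4 ± 34.5 to 3150.5 ± 1817 (6.13 ± 0.49, adjusted p = 3.8e-08). Tbx21 rose from 49.2 ± 19.7 to 369 ± 103 (2.92 ± 0.36, adjusted p = 2.0e-05), Cxcr3 from 55.3 ± 33.0 to 391 ± 115 (3.04 ± 0.42, adjusted p = 9.4e-05) and Cd44 from 5.99 ± 8.91 to 194 ± 20.6 (5.58 ± 0.52). Itgae fell from 218 ± 46.8 to 3.34 ± 3.49 (-6.05 ± 0.50, adjusted p = 5.8e-08) and Ccr9 from 317 ± 107 to 6.70 ± 3.85 (-5.43 ± 0.42, adjusted p = 1.9e-08). The groups did not overlap for 371 genes (3.93%, against 0.794% by chance).

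Of the fixed lists, the memory and effector-memory genes rose, 20 of 28 with 1 lower (22 and 2 adjusted over the list alone; median 2.15, adjusted p = 1.2e-30). The lower gene was Itga4, which encodes the integrin chain CD49d (-1.36). Natural killer receptors rose in 10 of 15 with 1 lower (14 and 1 adjusted over the list alone; median 2.45, adjusted p = 3.2e-23), with Klrc1 at 82.1 ± 38.8 in memory cells. The lower member was Cd226 (-0.94), an adhesion receptor gene chosen after its value was seen and kept in 2 of 10 fits that left out a library (adjusted p up to 0.117, without memory library 5). Cytotoxic molecules rose in 10 of 17 (11 adjusted over the list alone; median 1.21, adjusted p = 9.7e-19), including Prf1, the pore-forming perforin, by 1.69. Naive and quiescence genes fell in 5 of 21 (9 lower and 2 higher adjusted over the list alone; median -0.56, adjusted p = 4.7e-09). Inhibitory receptors rose in 2 of 8 (6 higher and 1 lower adjusted over the list alone; median 1.02, adjusted p = 1.8e-04), namely Entpd1 (3.68) and Lair1 (1.70). NK and innate lymphocyte markers rose in 5 of 7 (7 adjusted over the list alone; median 2.45, adjusted p = 7.8e-14). Ncr1, Tyrobp and Klrb1f, under the filter, averaged 0.681, 2.935 and 1.539 in these memory cells, so NK cells in the sort are not shown here either. These 6 lists hold with an estimated correlation.

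A further set of lists passed only with the preset correlation. Ribosomal protein genes had a median of 0.71 with no member called (adjusted p = 1.1e-14; adjusted p = 0.40 with an estimated correlation). Mitochondrially encoded genes had a median of 0.48 (0.0045; adjusted p = 0.40 with an estimated correlation) and oxidative phosphorylation genes 0.23 (0.0064; adjusted p = 0.58 with an estimated correlation). Glycolysis genes had a median of 0.31 (0.029; adjusted p = 0.43 with an estimated correlation) and the CD4 and regulatory T cell markers 0.61 (0.0084; adjusted p = 0.062 with an estimated correlation). Chemokine receptors had a median of 0.37 (0.013; adjusted p = 0.10 with an estimated correlation) and cytokine receptors 0.18 (0.029; adjusted p = 0.35 with an estimated correlation). Interferon-stimulated genes had a median of -0.07 (adjusted p = 0.013; adjusted p = 0.22 with an estimated correlation), with 4 of 34 lower (7 adjusted over the list alone). Among them were Zbp1 (-1.45), Igtp (-0.92) and Gbp2 (-1.19). The Gbp2 call was kept without naive library 3 or memory library 4 but in no other of the 10 fits that left out a library (adjusted p up to 0.115). Cell cycle genes were not called (median 0.03, adjusted p = 0.55), and Mki67 was 5.41 ± 6.15 in naive and 5.18 ± 2.67 in memory cells. TCR signal strength reporters were not called either (median 0.12, adjusted p = 0.43), with Ccl4, Xcl1 and Ly6c1 higher and Egr2 (-2.07) and Izumo1r lower. Izumo1r was chosen after its value was seen and kept in 4 of 10 fits that left out a library (adjusted p up to 0.152, without memory library 3). The gamma delta and natural killer T cell markers had a median of -0.81, a mean of 0.14 and no call (adjusted p = 0.85), with Cd163l1 (3.16) higher and Trdc (-1.52) lower.

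The 2 memory comparisons shared 110 higher genes (3.13 by chance from lists of these sizes) and 39 lower genes (0.640 by chance), and Trdc was called in opposite directions. Its wild-type call was lost without naive library 1 or 2 or memory library 2, 3 or 4 (adjusted p up to 0.0848) and its Dock2-deficient call without naive library 1 or 4 or memory library 3 (up to 0.0599). Over the 354 genes called in either genotype the fold changes had r = 0.888 and rho = 0.875 across genes, which are not independent replicates, and 97.2% had the same sign. These genes were picked by the fold changes compared, and over all 9437 genes r was 0.517 and rho 0.262, with the same sign in 57.4%. Among the shared genes, Ramp1 (-3.36 and -3.07), Rgcc (-3.79 and -3.33) and Igfbp4 (-3.84 and -4.66) were lower and Ctla2a (5.21 and 5.92) and Il2rb (3.63 and 2.77) higher in wild type and Dock2-deficient mice respectively. Without wild-type memory library 4 and Dock2-deficient memory library 5, the counts were 207 and 258 genes.

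**Figure D2:**
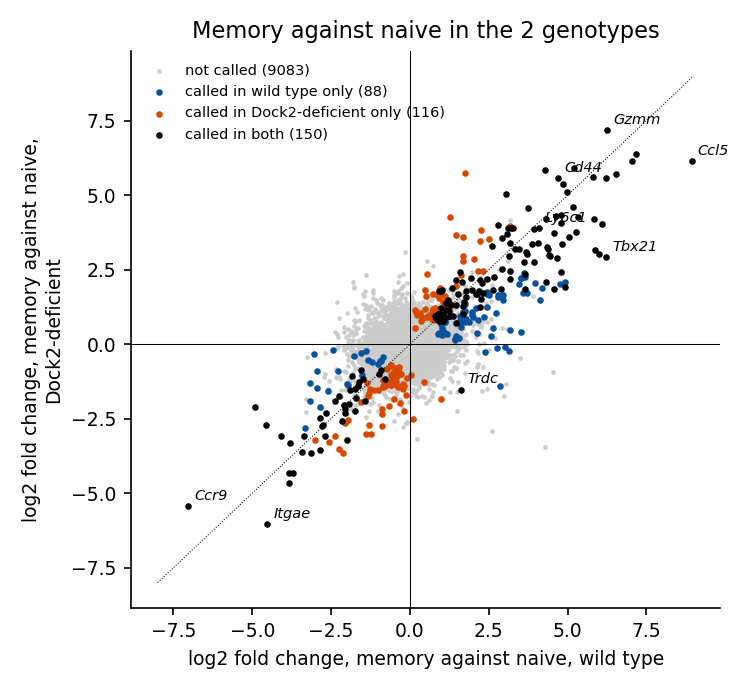
Log2 fold change of memory against naive cells in wild type (horizontal axis) and Dock2-deficient mice (vertical axis), with each point a gene, coloured by the genotype in which it was called. The called genes lie along the diagonal (r = 0.888 over these 354 genes, 0.517 over all 9437), and Trdc lies on opposite sides of 0.

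Naive cells of Dock2-deficient mice differed from wild-type naive cells in 13 genes, 12 higher and 1 lower, of which 12 changed at least 2-fold. Genes of memory cells were among those higher: Tbx21 (chromosome 11, 97098071 to 97115331) was 7.44 ± 7.24 (SD, n = 4) in wild type and 49.2 ± 19.7 (SD, n = 5) in Dock2-deficient cells (log2 fold change 2.82 ± 0.38, adjusted p = 6.5e-04). Cxcr3 (chromosome X, 101731535 to 101734269) rose by 3.37 ± 0.45 (adjusted p = 6.5e-04) and Ccl5 (chromosome 11, 83525778 to 83530518) from 3.29 ± 2.48 to 46.4 ± 34.5 (adjusted p = 0.0016). With only the libraries compared in the fit these 3 calls were lost (adjusted p = 0.0633 for Tbx21 and Cxcr3 and 0.0751 for Ccl5), as they were with voom weights (0.394, 0.412 and 0.496). The 3 levels stayed below those of wild-type memory cells (509, 284 and 1733). Lgals1, which encodes galectin-1, rose from 33.5 ± 11.02 to 117 ± 12.5 (1.82 ± 0.26, adjusted p = 9.7e-04).

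Some genes linked to gamma delta T cells were also higher. Trdc, the constant segment of the T cell receptor delta chain (chromosome 14, 54142851 to 54148868), rose from 3.98 ± 1.34 (SD, n = 4) to 32.8 ± 11.5 (SD, n = 5; 2.73 ± 0.37, adjusted p = 6.5e-04). Cd163l1 (chromosome 7, 140218267 to 140231145) was listed at 0 in all 4 wild-type naive libraries and at 9.23 ± 3.28 in Dock2-deficient ones (adjusted p = 6.6e-05). It averaged 61.9 and 89.5 in wild-type and Dock2-deficient memory libraries, so it does not tell gamma delta T cells from memory cells. Cxcr6, of the same fixed list, went from 161 to 75.8. Under the filter, Sox13, Zbtb16 and Blk averaged 0.551, 0 and 0 in wild-type and 0.364, 0.184 and 0.182 in Dock2-deficient naive libraries. The gamma delta and natural killer T cell markers rose, 2 of 6 (4 higher and 1 lower adjusted over the list alone; median 2.26, adjusted p = 2.5e-06). So did the memory and effector-memory genes, 3 of 28 (7 adjusted over the list alone; median 0.25, adjusted p = 8.2e-05). Both hold with an estimated correlation (adjusted p = 0.033 in each). That call was lost for the memory list without wild-type naive library 3 or 4 or Dock2-deficient naive library 3 (adjusted p up to 0.0965) and for the gamma delta list without wild-type naive library 3 (0.0701). Dock2-deficient naive library 2 stood apart on the memory list, with a mean log2 value of 5.53 against 4.733 to 4.816 in the other 4 and 4.37 on average in wild type. Without it the median was 0.17 (adjusted p = 0.0039, and 0.0345 with an estimated correlation).

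Interferon-stimulated genes rose in 3 of 34 (5 adjusted over the list alone; median 0.18, adjusted p = 0.029; adjusted p = 0.31 with an estimated correlation). Igtp, an interferon-inducible GTPase, rose by 1.16 ± 0.22 (adjusted p = 0.0279) and Ly6a, the gene of the surface protein Sca-1, by 2.34 ± 0.43 (adjusted p = 0.0214). Both calls were lost without certain libraries. For Igtp these were wild-type naive library 2, 3 or 4 or Dock2-deficient naive library 2, 3, 4 or 5 (adjusted p up to 0.127). For Ly6a they were wild-type library 2 or 4 or Dock2-deficient library 2, 4 or 5 (up to 0.119).

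Fcgrt, which encodes the heavy chain of the neonatal Fc receptor (chromosome 7, 45092990 to 45103851), rose from 26.6 ± 4.11 to 87.1 ± 19.1 (1.65 ± 0.23, adjusted p = 8.7e-04). Pydc3, a member of the interferon-inducible Ifi200 family (chromosome 1, 173673675 to 173698395), fell from 504 ± 134 to 134 ± 12.7 (-1.87 ± 0.22, adjusted p = 1.9e-04). A further 2 genes were chosen after their values were seen. Chst11, a sulfotransferase gene, was 0.275 and 7.34 (adjusted p = 0.0122, and 0.0519 without wild-type naive library 2). The gene 5830411N06Rik was listed at 0 in all wild-type naive libraries and at 11.99 ± 12.7 in Dock2-deficient ones (adjusted p = 0.0407). It was kept in 2 of the 9 fits that left out a library (adjusted p = 0.132 without Dock2-deficient naive library 5). Cd44 and Il2rb were not called, nor were the TCR reporters Cd5 (0.62, adjusted p = 0.257) and Nr4a1 (-0.90, adjusted p = 0.789).

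Immediate early and stress genes had a median of -0.49 (adjusted p = 5.5e-04; adjusted p = 0.43 with an estimated correlation) and oxidative phosphorylation genes 0.17 (adjusted p = 0.0026; adjusted p = 0.54 with an estimated correlation). No member of either was called. The mean log2 value of the immediate early list ranged from 5.27 to 7.73 in Dock2-deficient and from 7.46 to 7.69 in wild-type naive libraries. The groups thus overlapped, with a wide spread in the Dock2-deficient one. The DOCK and Rac pathway list was not called (median 0.02, adjusted p = 0.63), nor were TCR proximal signalling components (-0.04, adjusted p = 0.86). The same held for TCR signal strength reporters (0.31, adjusted p = 0.15), survival and apoptosis genes (median -0.10, mean 0.08, adjusted p = 0.90) and the substrain genes (-0.61, adjusted p = 0.20). Markers of other cells were uneven in level. The red cell gene Hbb-bs averaged 0.213 in wild-type and 25.3 in Dock2-deficient naive libraries, and the immunoglobulin gene Igkc 7.56 and 124 (highest library 550.3); both were picked after their values were seen. Neither the red cell list (median 1.64, adjusted p = 0.10), the B cell list (0.33, adjusted p = 0.35) nor the myeloid list (-0.03, adjusted p = 0.99) passed. These tests say little, since 2, 5 and 2 members were above the filter. Untested myeloid genes listed at 0 in wild-type naive libraries averaged 3.23 (Lyz2), 3.81 (S100a8), 4.01 (S100a9) and 3.25 (Mpeg1) in Dock2-deficient ones, with highest libraries of 10.19 to 19.02.

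The genotype comparison in naive cells had 256 genes without overlap (2.71%, against 1.59% by chance). With sex as a covariate the 13 fold changes kept their sign, with a median size of 2.474 against 2.732 without it, and the median SE went from 0.370 to 0.465. Over all genes 3 of the 13 passed (Cd163l1, Pydc3 and Trdc). All 13 passed adjusted over these genes alone, which had been chosen by the same contrast. Tbx21 went from 2.82 to 2.90 and Ly6a from 2.34 to 1.13. Of the lists called in naive cells, the interferon, immediate early and oxidative phosphorylation lists no longer passed with this covariate. The memory and gamma delta lists still did. The fit with sex rests on 1 female Dock2-deficient library in each state. With voom weights 3 of the 13 stayed past the threshold over all genes (Fcgrt, Pydc3 and Lgals1).

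**Figure D3:**
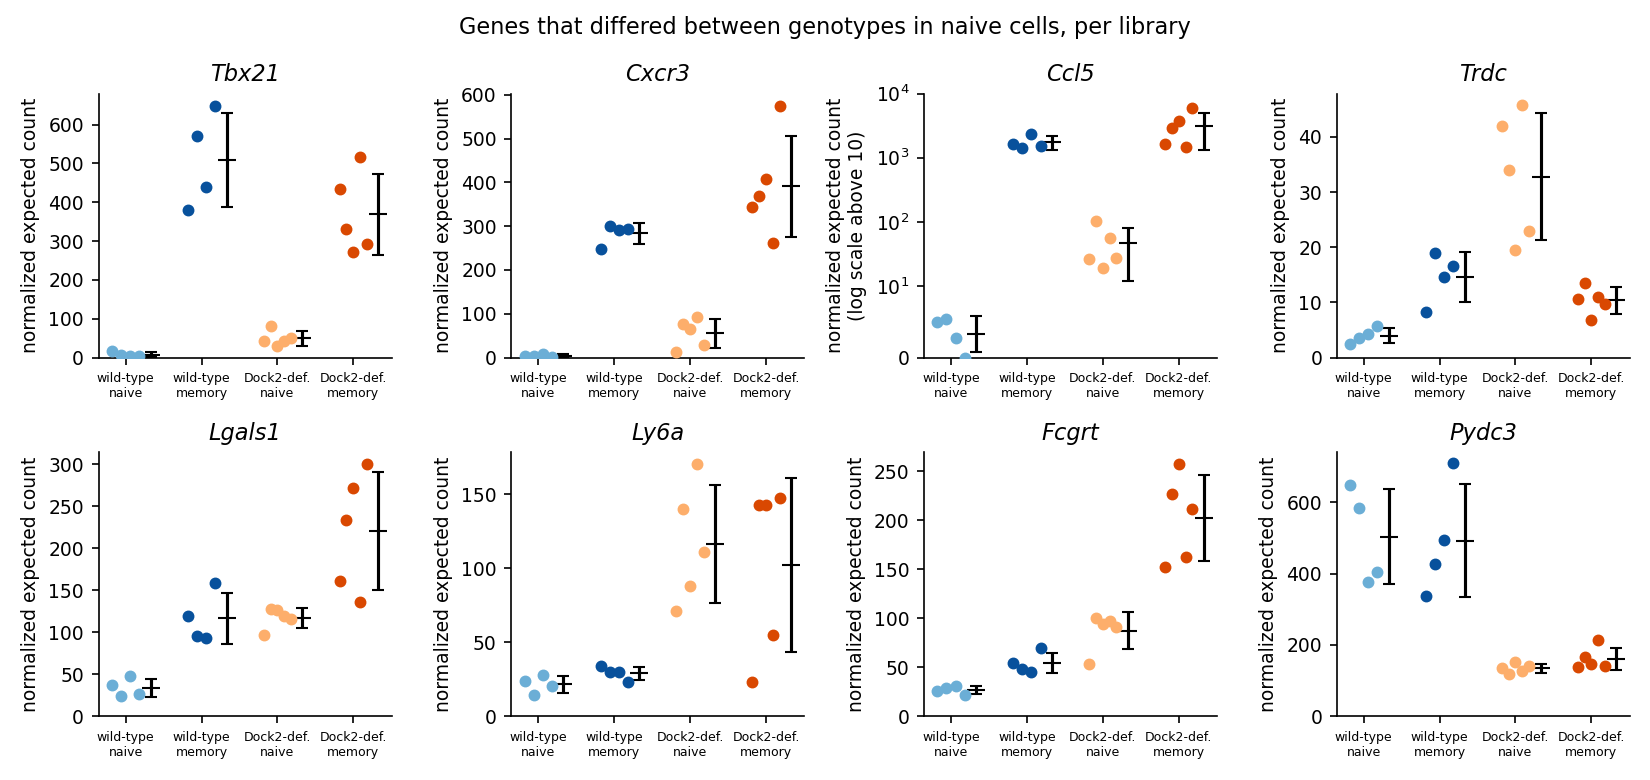
Normalized expected counts of 8 genes called between genotypes in naive cells, with each point a library and bars giving mean ± SD per group (n = 4 or 5); Ccl5 is on a log scale above 10. Tbx21, Cxcr3, Ccl5, Trdc, Lgals1, Ly6a and Fcgrt are higher, and Pydc3 lower, in Dock2-deficient naive libraries.

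Memory cells differed between genotypes in 5 genes, 3 higher and 2 lower in Dock2-deficient mice, all at least 2-fold. Fcgrt rose from 54.1 ± 10.6 (SD, n = 4) to 202 ± 44.2 (SD, n = 5; 1.87 ± 0.23, adjusted p = 3.8e-04). Pydc3 fell from 493 ± 160 to 161 ± 31.6 (-1.57 ± 0.22, adjusted p = 0.0018). Klra8, which encodes the activating receptor Ly49H (chromosome 6, 130115226 to 130129898), was 3.08 ± 2.12 in wild-type and 56.4 ± 20.9 in Dock2-deficient memory cells (3.98 ± 0.63, adjusted p = 0.0082, lost without Dock2-deficient memory library 3, at 0.0746, or library 5). The call was also lost with a pseudocount of 0.5 and with a filter of 50. It was lost too without wild-type memory library 4 and Dock2-deficient memory library 5 together. Other Klra copies, none called, went both ways between wild-type and Dock2-deficient memory cells. Klra7 was 75.9 and 23.3 and Klra6 77.4 and 51.7, while Klra4 was 7.68 and 33.7 and Klra3 28.9 and 49.6. Reads shifted between near-identical copies were thus not told apart from a rise of Klra8. A pair of genes was chosen after their values were seen. Tmie, known for its part in hair cell hearing (chromosome 9, 110865711 to 110880113), was 0.637 in wild-type and 10.6 in Dock2-deficient cells (2.90 ± 0.35, adjusted p = 3.8e-04). Gm43056, an unnamed gene model (chromosome 5, 86683850 to 86686640), was 15.4 and 1.31 (adjusted p = 0.0244). It was kept in 3 of 9 fits that left out a library (adjusted p = 0.120 without wild-type memory library 3).

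Memory genes as a group did not pass in memory cells (median -0.26, adjusted p = 0.61). Tbx21 (-0.47, adjusted p = 0.523), Gzmm (1.47, adjusted p = 0.246), Klrk1 (-1.70, adjusted p = 0.238) and Mki67 (-2.00, adjusted p = 0.254) were not called. Ribosomal protein genes had a median of 0.83 with none of 47 called (adjusted p = 1.4e-17; adjusted p = 0.49 with an estimated correlation) and oxidative phosphorylation genes 0.44 (1.7e-07; adjusted p = 0.49 with an estimated correlation). With upper quartile scaling the median over all genes was 0.12 in this comparison and 0.11 in the interaction. Natural killer receptors had a median of -0.51 (3 lower adjusted over the list alone, none over all genes; adjusted p = 0.020; adjusted p = 0.51 with an estimated correlation). Gamma delta and natural killer T cell markers had a median of -1.56 (4 lower adjusted over the list alone, none over all genes; adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation). Glycolysis genes (0.36, adjusted p = 0.020; adjusted p = 0.51 with an estimated correlation) had no member called. Immediate early genes (-0.49, adjusted p = 0.0096; adjusted p = 0.66 with an estimated correlation) had none over all genes and 1 lower adjusted over the list alone. Their mean log2 value ranged from 4.90 to 8.44 in Dock2-deficient and from 7.65 to 8.36 in wild-type memory libraries, so these groups overlapped too. The substrain genes (-0.62, adjusted p = 0.19) and the DOCK and Rac pathway list (median 0.11, adjusted p = 0.83) did not pass. Groups did not overlap for 419 genes (4.44%, against 1.59% by chance).

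The count in memory cells moved with single libraries: it was 12 without Dock2-deficient memory library 1, 8 without library 4 and 3 without library 3. For the genes changed, Dock2-deficient against wild type in memory cells, limma with sex as a covariate called 0 (598 at an unadjusted p under 0.05). Voom weights gave 6, among them 3 of the 5 (Tmie was lost at adjusted p = 0.219 and Gm43056 at 0.231). With only the libraries compared 2 of the 5 were kept, Fcgrt and Klra8 (Pydc3 0.0525, Tmie 0.276 and Gm43056 0.327).

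The genotype effect differed between naive and memory cells in 3 genes. Tbx21 was higher in Dock2-deficient naive cells and not in memory cells (interaction -3.29 ± 0.54, adjusted p = 0.0287), and Trdc likewise (-3.16 ± 0.52, adjusted p = 0.0287). Tmie, chosen after its values were seen, went the other way (2.82 ± 0.50, adjusted p = 0.0495). For Ccl5 (-2.80, adjusted p = 0.626), Cxcr3 (-2.95, adjusted p = 0.221) and Cd163l1 (-2.71, adjusted p = 0.0507) a difference between the states was not called. The interaction was negative for the memory and effector-memory genes (median -0.49, adjusted p = 6.9e-05; 1 of 28 lower over all genes, 4 adjusted over the list alone). It was also negative for the TCR signal strength reporters (-0.50, adjusted p = 0.0015; none over all genes or adjusted over the list alone) and the gamma delta and natural killer T cell markers (-2.94, adjusted p = 1.8e-11; 1 of 6 lower over all genes, 4 adjusted over the list alone). These 3 hold with an estimated correlation (adjusted p = 0.024, 0.017 and 0.0036). The mean log2 value of the TCR signal strength reporters was 4.86 in wild-type and 5.06 in Dock2-deficient naive cells. In memory cells it was 5.78 and 5.25, so the larger part of this interaction lay there.

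The interaction calls were fragile. With the replicate number as a block, limma kept 0 of the 3. Tbx21 was called in 5, Trdc in 2 and Tmie in 1 of the 18 fits that left out a library. Adjusted p was up to 0.0936 and 0.109 without Dock2-deficient naive library 4 and 0.1405 without Dock2-deficient memory library 2. Across all 9437 genes the genotype effects in naive and memory cells had r = 0.273 and rho = 0.233, with the same sign in 59.0%. The value of r was 0.151 without wild-type naive library 1 and 0.167 without Dock2-deficient naive library 4. The called genes shared between them were Fcgrt, higher (0.00381 by chance), and Pydc3, lower (0.000212 by chance).

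**Figure D4:**
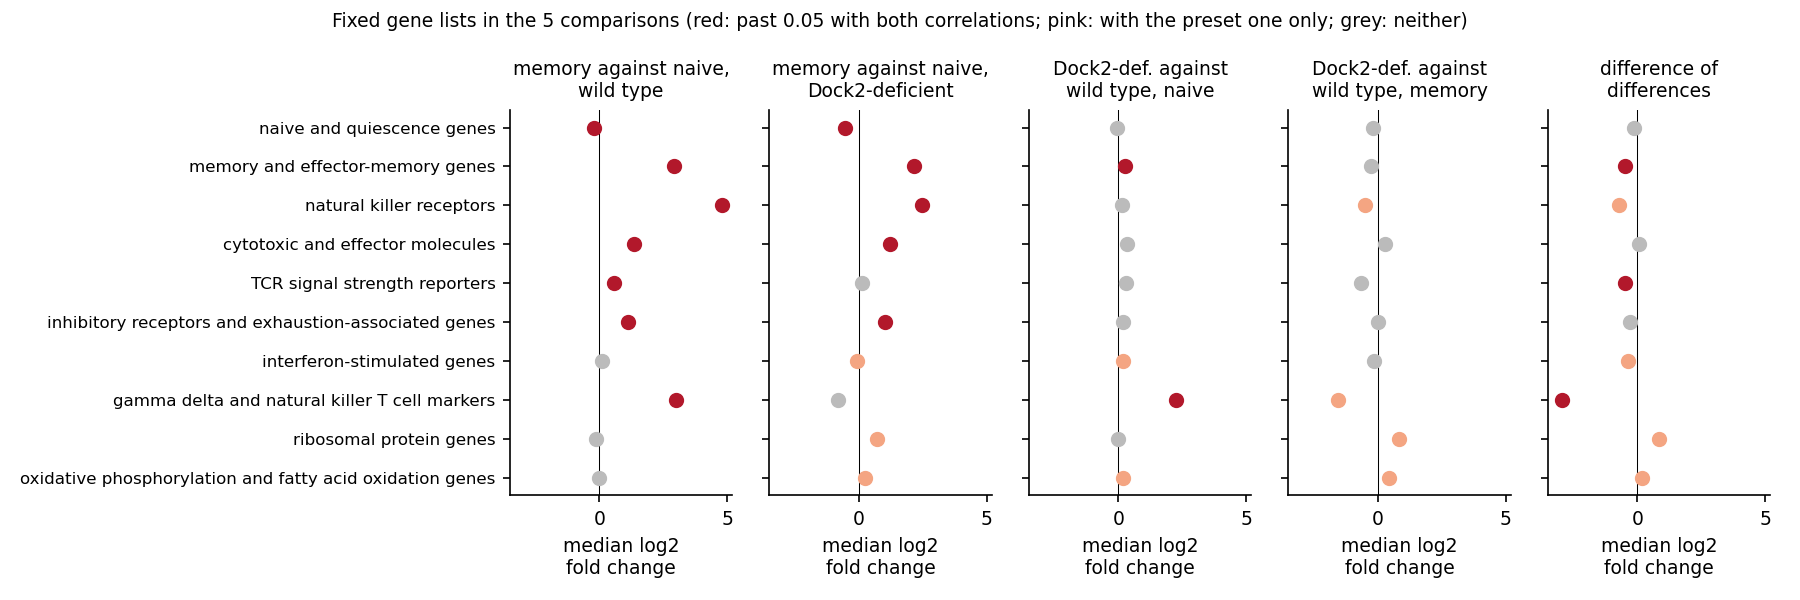
Median log2 fold change of 10 fixed gene lists in the 5 comparisons, with points in red where a list passed 0.05 with both the preset and the estimated correlation, pink where it passed with the preset one alone and grey where it passed with neither. The memory and gamma delta lists are red in the naive genotype comparison and in the interaction, and no list is red in the memory genotype comparison.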

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

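All tests of the first and second pattern below, the requirement on the spread in the third and the covariate for the share of Rn18s-rs5 were chosen only after the results were seen. Some of these tests were changed. The rule for fewer captured molecules and the measure of other cell types in the second pattern were replaced after their first outcome, and the test of memory cells in the first was rewritten after the gene values had been seen. Other versions of the memory cell test were tried after its first outcome, which had left the explanation open. Without the called genes (21 genes, median 2.364%, interval 0.854 to 5.456) and with the bound set on the group it would have been excluded. Over 26 genes that bound was met as well, but with Ccl5 left out the interval reached 10.31%, the share needed, so the verdict hung on the choice of genes and the rule of the first run was kept. Trdc was later taken out of the constant genes counted for gamma delta T cells, since it is the gene to be explained.

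Memory-associated genes were higher in Dock2-deficient naive libraries, and memory cells inside the naive gate, gamma delta T cells or the sex of the mice could have brought this about. Shares were scaled from the wild-type naive to the Dock2-deficient memory mean. Tbx21, Cxcr3 and Cd163l1 would need a share of 10.31% to 13.23% of memory cells. The 26 genes at least 8-fold higher in wild-type memory cells, with a Dock2-deficient memory mean of at least 50, implied a median of 2.715% (95% bootstrap interval 1.225 to 8.686). They included these 3 genes and the sorting marker Cd44, and the interval treats genes as independent. Gzmm (0.3505%) and Ctla2a (0.126%) implied less. This argues against cells like the average memory library as the whole cause, while memory cells unlike that average were not tested. Memory cells stay open, since 4 of the 21 genes not called between genotypes (Anxa2, Cxcr5, Slamf7 and Zfp296) implied 10.31% or more and the intervals of Dock2-deficient naive libraries 1 (up to 3.108, needed 2.462), 2 (12.29, needed 8.351) and 3 (6.507, needed 5.874) reached the share needed there. Ccl5 implied 1.369%, inside the wide interval of the other 25 genes (1.08 to 10.31), which fits a small share of memory cells. For Trdc the other 2 of 2 constant genes tested, Tcrg-C2 and Tcrg-C4, were higher adjusted over the list alone (adjusted p = 0.0012 for each, 0.199 and 0.209 over all genes). Gamma delta T cells in the sort would give this, but the test does not single them out. Both genes were also higher in wild-type memory than in wild-type naive cells (25.91 against 2.408 and 12.87 against 1.196). In Dock2-deficient mice they averaged 9.002 and 4.102 in memory cells, below the naive means. Gamma delta T cells thus stay open. With sex as a covariate the median size of the 13 fold changes went from 2.732 (SE 0.370) to 2.474 (SE 0.465) and 3 of the 13 calls stayed past the threshold over all genes, but these genes were chosen by the contrast tested and the fit rests on 1 female Dock2-deficient library in each state, so sex, substrain and an effect of Dock2 itself stay open.

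Wild-type memory library 4 stood apart on the second principal component. Fewer captured molecules may be the cause, since 6 genes that the other libraries of its group held at 50 or more were listed at 0 (0 to 7 in the other libraries, median 0), but Dock2-deficient memory library 4 had 7, so this stays open. Its depth outside Rn18s-rs5 and the mitochondrial ribosomal RNA genes was 1.57 megareads, close to the median of 1.547 (0.774 to 2.64 over the libraries). The library with the lowest such depth, Dock2-deficient memory library 1, lay at 7.87 on that component. Both argue against lower sequencing depth as the cause, though the bound at the median was passed by a small margin. Cells of another type stay open: the largest ratio of summed values of 6 marker lists to the highest other library of the group was 1.244, but genes that memory cells hold at 50 or more carried up to 95.02% of a sum, which would hide a small share. A difference of the mouse itself was not tested.

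Ribosomal protein genes had a median of 0.83 in Dock2-deficient against wild-type memory cells, and a trend with transcript length or a single library could lie behind it. The median was 0.5275 after the length trend was removed and 0.5933 without Dock2-deficient memory library 5. Both exceed the bound of 0.5 of the first value that was written beforehand, which taken alone would have excluded both explanations. With 1 more memory library left out, however, the values ranged from 0.403 to 0.665 and from 0.298 to 0.791, which reaches below that bound, so both were left open. An effect of genotype on ribosomal protein genes also remains possible and was not tested apart.

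The libraries were also split into groups of the same sizes in other ways, and the number of called genes was compared. For memory against naive in wild type (238 genes, highest other split 1) only the real split called as many. That is 1 of 35, the smallest share that 35 splits can give. For naive cells between genotypes (13, highest other 1) it was 1 of 100. Both counts argue against an arbitrary grouping of these libraries. The labels do not say that replicates were separate animals, so chance differences between mice are not excluded. For the interaction 1 of 100 splits called as many (3, highest other 2), a margin of 1 gene on a count that fell to between 0 and 2 whenever a library was left out, so this split carries little weight. For memory against naive in Dock2-deficient mice 2 of 100 splits called as many as the real one (266, highest other 649), and for memory cells between genotypes 4 of 100 (5, highest other 143). Splits that call several times the real count point to a structure of the samples. The split with 649 genes set the libraries with at most 58.2% of Rn18s-rs5 against those with at least 61.6%, and with that share as a covariate the counts were 281 and 9.

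In 30 of 407 sets of values (7.37%) a library lay apart from the others of its group by Dixon's test. In 7 of these all other libraries of the group were at 0, where the rate of about 1 in 20 expected by chance does not hold, and without them the share was 5.75%. Of the 30, 6 were in wild-type memory library 4. In it Cd44 was 124.1, Klra7 45.28, Klra8 0, Klre1 13.11, Plek 73.43 and Txk 738.7. In wild-type memory library 1 Cxcr3 was 248.7 and Klrc1 75.61. In wild-type naive library 1 depth was 6.842 megareads, and the mean of the TCR signal strength reporters was 5.168. In wild-type naive library 2 Fcer1g and Klra7 were each 1.808, in library 3 Ccr2 and Gzmm were each 2.795, and in library 4 Stmn1 was 11.29.

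In Dock2-deficient naive library 2 Ccr2 was 2.724, Ctla2a 25.84, Gas7 19.55 and Klrb1c 1.359, and the mean of the memory and effector-memory genes was 5.53 (4.733 to 4.816 in the others). In Dock2-deficient naive library 1 Fcgrt was 53.65 and Klra3 0.9092, in library 3 Cd101 was 2.56, and in library 4 Txk was 235.8. In Dock2-deficient memory library 1 Gbp2 was 37.28 and the mean of the gamma delta and natural killer T cell markers 3.081. In Dock2-deficient memory library 2 Klra8 was 22.55 and Ramp1 8.645, and in library 4 Plek was 400.1.

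The interaction was -3.294 for Tbx21, -3.159 for Trdc and 2.816 for Tmie. For the lists its median was -0.4926 for memory and effector-memory genes, -0.5003 for TCR signal strength reporters and -2.935 for gamma delta and natural killer T cell markers. It was -0.7346 for natural killer receptors (adjusted p = 0.43 with an estimated correlation), -0.3459 for interferon-stimulated genes (0.22) and 0.201 for oxidative phosphorylation genes (0.77). It was 0.8308 for ribosomal protein genes (0.45) and -1.17 for CD4 and regulatory T cell markers (0.17).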

How the results depend on the processing

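The count of genes changed, memory against naive in wild type, went from 238 to 140 with a filter of 50 and 377 with library weights, and ranged from 185 to 211 when each library was left out in turn. For genes changed, memory against naive in Dock2-deficient mice, it went from 266 to 450 with library weights and ranged from 200 to 314 without single libraries. For genes changed, Dock2-deficient against wild type in naive cells, the count went from 13 to 8 with only the libraries compared, 6 with voom weights, 3 with sex as a covariate and 22 with the share of Rn18s-rs5 as a covariate, and ranged from 9 to 19 without single libraries.

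For genes changed, Dock2-deficient against wild type in memory cells, the count went from 5 to 12 with a pseudocount of 5, 10 without a filter, 2 with a filter of 50, 3 with only the libraries compared, 40 with library weights and 9 with the share of Rn18s-rs5. It was 0 with sex as a covariate in limma, where 598 genes had an unadjusted p under 0.05, and ranged from 3 to 12 without single libraries. For the genes changed, interaction of genotype and cell state, the 3 calls became 1 with a filter of 50 and with the share of Rn18s-rs5 and 5 with library weights. In limma 0 were called without a filter (1005 at an unadjusted p under 0.05), with voom weights (484) and without wild-type memory library 4 and Dock2-deficient memory library 5 (335). The range without single libraries was 0 to 2. The cause of these shifts was not tested.

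The correlation of genotype effects in naive and memory cells went from 0.273 to 0.377 with a filter of 50 and 0.436 with sex as a covariate, and ranged from 0.151 to 0.336 without single libraries. Single genes were not followed under robust moderation and library weights. In the other settings, the Dock2 level per library, Dock2-deficient against wild type in naive cells, passed limma's threshold only with the share of Rn18s-rs5 as a covariate (-0.90, adjusted p = 0.033). The same held for the Dock2 level per library, Dock2-deficient against wild type in memory cells (-1.23, adjusted p = 0.0037). Without single libraries its log2 fold change ranged from -0.88 to -0.56 in naive and from -1.83 to -1.28 in memory cells.

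With the replicate number as a replicate block the counts were 196, 218, 19 and 7, and limma called 0 of the genes changed, interaction of genotype and cell state (473 at an unadjusted p under 0.05). In the memory and interaction fits the block was the number within a genotype. In the genotype fits (19 and 7) it was the number alone, shared by both genotypes, which does not stand for a mouse. The labels do not tie a number to an animal, and correlations between same-numbered libraries after removal of group means ran from -0.253 to 0.303, so the numbers were not taken as pairs. Of the 9 naive libraries, 4 correlated best with the memory library of their own number and genotype, and the female library of both Dock2-deficient groups is number 1. The column names also number the naive and memory libraries in the same order of genotype and replicate. Shared mice are therefore not ruled out. If mice were shared, the main memory and interaction p-values ignore that pairing, and the fit with the block, with 0 interaction calls, applies. Calls lost with the block are not in themselves evidence of weaker effects.

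Over the named genes, 1559 of 1659 values with another setting kept their call, 100 lost it and 0 reversed. Robust moderation and library weights are not among these settings. Without single libraries 139 of 1194 lost it. Of the 238 and 266 genes called between memory and naive cells, 93 and 92 were lost in at least 1 fit that left out a library. Over the lists, 292 of 360 kept it, but 21 of 45 list results kept it in every setting, and the estimated correlation cost the most (23 lost). Count models on rounded expected counts were not run.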

Other observations

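The scavenger receptor genes Cd163l1 and 5830411N06Rik lie next to each other on chromosome 7 (140218267 to 140231145 and 140247284 to 140300736), and both were higher in Dock2-deficient naive cells. The latter, chosen after its values were seen, was 23.6 ± 7.31 (SD, n = 4) in wild-type memory and 106.9 ± 14.9 (SD, n = 5) in Dock2-deficient memory cells, and the groups did not overlap, but limma did not call it (2.17, adjusted p = 0.228). Lgals1 reached 117 in Dock2-deficient naive cells, the level of wild-type memory cells (116).

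Tmie, chosen after its values were seen, was 45.0 in wild-type and 47.8 in Dock2-deficient naive cells and fell to 0.637 and 10.6 in memory cells. Ifngr1 and Ifngr2, the chains of the interferon gamma receptor, changed in opposite directions between naive and memory cells in both genotypes (1.54 and -3.83 in wild type, 1.70 and -4.34 in Dock2-deficient mice). Plek, which encodes the cytoskeletal signalling protein pleckstrin, was listed at 0 in all wild-type naive libraries and averaged 152 in wild-type and 302.3 in Dock2-deficient memory cells. Limma did not call this difference between genotypes. Library 4 lay apart in both groups, at 73.43 in wild type (others 168.3 to 190.1) and 400.1 in Dock2-deficient mice (others 257.8 to 289.3).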
